A study of Homo sapiens with 5 samples.

How the data were processed

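Gene expression of MCF7 cells was measured by RNA sequencing of poly(A)-selected RNA in 5 libraries, 1 for each of 5 groups named by the labels. The submitters' processing notes name FastQC, Trimmomatic, STAR, featureCounts and the GRCh38 genome build, with no versions, settings or order. The labels leave open whether the libraries were strand-specific, so reads of a gene overlapped by another on the opposite strand cannot be assigned with certainty. The count table deposited by the authors holds raw gene counts for 58735 genes of GENCODE release 29, with 1 column per library. Per the file headers, the authors also deposited FPKM for each library, a count scaled by gene length and by a library total that is not given. The total that the FPKM values imply was 1.36, 0.967, 1.49, 1.03 and 1.46 times the summed counts of MCF7_E2, ED, LTED, LTED_abemaciclib and LTED_666-15. Counts and FPKM matched within 0.1% for every gene except CCND1 in MCF7_E2 and NR2F1 in MCF7_E2, ED and LTED_abemaciclib, so values of these genes were also computed from the counts that FPKM implies.

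Counts were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.970, 0.896, 1.08, 0.970 and 1.09 in the order above. Log2 ratios of the scaled CPM (counts scaled to a common library total) used a prior count of 2. Genes were tested where either library of a comparison reached 1 CPM, and 16274 genes reached it in any library. A gene was called higher or lower at a log2 ratio of at least 1 in size whose 95% Clopper-Pearson counting interval excluded a ratio of 1. No test between groups was made and no p-value is given, because 1 library per group leaves no spread. Intervals and floors cover counting error only. Reads without molecular identifiers are not independent molecules, so these intervals are too narrow as statements about molecules. A gene with 0 counts in 1 library was given a fold against a floor of 3 counts in that library, which is 0.194, 0.109, 0.172, 0.101 and 0.167 CPM in the order above.

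Before the data were examined, 31 gene lists, 5 comparisons, 2 overlaps, the thresholds and the rule for named genes were fixed; 1 list member was not found in the table. A list's members with at least 1 CPM in any library were summarized by the median log2 ratio. Its percentile among 10000 random lists, drawn from 20 bins of expression, set the list apart below 2.5 or above 97.5; lists with fewer than 5 measured members were given as values. Lists can share genes, and their members are not independent of each other. Named genes were the 8 highest and 8 lowest called coding genes with a mean of at least 10 CPM, 3 members of each list standing apart with a mean of at least 5 CPM, and a fixed set of CREB, estrogen receptor and cell cycle genes; the text gives a selection of them. Any other named gene, such as NR2F1, was chosen after its values were seen.

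Alternatives planned before the data were examined were DESeq2 1.42.0 size factors, scaling by total counts, prior counts of 0.5 and 10, a CPM minimum of 5 or none, a log2 ratio of at least 1.5, coding genes alone, log2(FPKM + 0.5) and log2(FPKM + 0.1), thinning to the lowest total, unmatched random lists, and overlaps without a shared library. Calls on FPKM used the size of the log2 ratio and the CPM minimum alone, without the counting interval. After the data were seen, a GC correction was added, which subtracts the median log2 ratio in 40 bins of transcript GC content. TMM factors without ED, calls without positional blocks and the FPKM-implied counts were also added then. Positional blocks were sought as medians of GC-corrected log2 ratios over 15 neighboring genes and compared with 200 shuffles of gene order. Leaving out a replicate and tests over several columns per library were not possible. No paired analysis was possible because each group has 1 library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the computation and matplotlib 3.10.9 for figures.

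The calling procedure was tested on simulated data with counting noise at the depth of each library. Of 100 genes changed 3-fold, 98 to 100 were recovered in each comparison, and all 100 changed 6-fold. Wrong calls made up 0.151% to 0.310% of genes tested, and 3% to 5.5% of 200 random lists stood apart. Such simulations hold no variation between cultures, so wrong calls from that source are not counted in them.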

Results

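Poly(A)-selected RNA was measured by RNA sequencing in 5 libraries of MCF7, an established estrogen receptor-positive human breast cancer cell line, with 1 library in each of 5 groups. MCF7_E2 was grown with estradiol (E2) and sampled at day 30, and ED was deprived of estrogen for 1 month. LTED, for long-term estrogen deprivation, was deprived for 13 months. LTED_abemaciclib combined the 13 months of deprivation with 8 months of 0.5 µM abemaciclib, an inhibitor of the cell cycle kinases CDK4 and CDK6. The treatment protocol speaks of abemaciclib resistant LTED cells. LTED_666-15 received 1 µM of the compound in its name, an inhibitor of the transcription factor CREB, for 24 hours. Total gene counts were 15926948 in MCF7_E2, 30576198 in ED, 16106269 in LTED, 30548938 in LTED_abemaciclib and 16407749 in LTED_666-15. With 1 library per group, no difference could be set against a spread between replicates, and "higher" and "lower" compare single libraries. A gene was called at a log2 ratio of at least 1 in size when its 95% counting interval excluded no difference. Numbers in parentheses after a fold are that interval, which covers counting error only.

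ED and LTED_abemaciclib, the libraries with the highest totals, differed from the other 3 along the GC content of genes. Across genes, the log2 ratio of each pair of libraries from different sets correlated with GC content at a Spearman coefficient of 0.286 to 0.512 in size. Pairs within a set stayed at 0.136 or below. ED vs MCF7_E2, LTED vs ED and LTED_abemaciclib vs LTED crossed the sets, so in these 3 comparisons the set and the condition cannot be told apart, and no fit with the set as a term was possible. LTED vs MCF7_E2 and LTED_666-15 vs LTED lay within a set. Log2 ratios also followed gene length, within a set as well. The Spearman coefficient was 0.172 in both LTED vs MCF7_E2 and ED vs MCF7_E2, and 0.140 in LTED_666-15 vs LTED. It was 0.083 in LTED_abemaciclib vs LTED and -0.056 in LTED vs ED. No correction for length was made. GC-corrected values are given for each list whose call the correction ended or made, and for the genes named here whose call it ended.

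**Figure D1:**
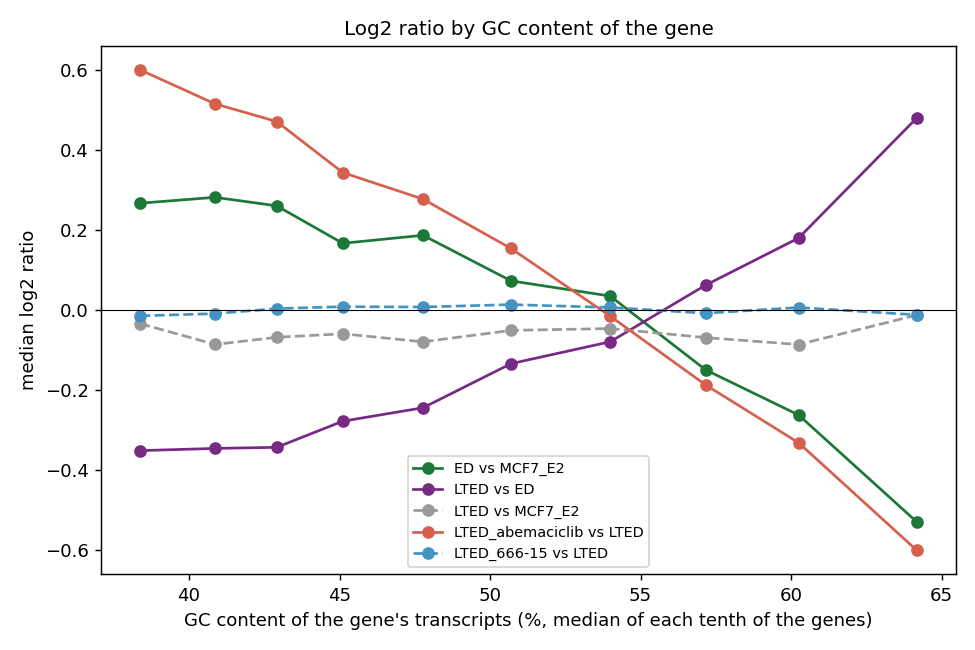
Median log2 ratio of genes (vertical axis) in 10 bins ordered by the GC content of their transcripts (horizontal axis, percent), one line per comparison of single libraries. LTED_abemaciclib vs LTED runs from 0.60 in the bin of lowest GC content to -0.60 in the highest, while LTED_666-15 vs LTED stays between -0.01 and 0.01.

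The comparison of ED with MCF7_E2 asks what 1 month without estrogen does to these cells. With 1 ED library, a response to deprivation cannot be told apart from a different culture of MCF7. By list medians, estrogen-induced, mitotic, amino acid response and hypoxia genes were lower in ED. Estrogen-repressed, interferon-stimulated, drug efflux, lysosomal and heat shock genes were higher by the same measure. Of 15305 genes tested, 2560 were higher and 2715 lower. ED was over 8-fold above all 4 other libraries at 96 genes and over 8-fold below them at 25. Mitochondrial rRNA made up 1.88% of its counts, against 0.636% to 1.05% in the others. The highest coding genes were IGFBP3, which encodes a binding protein of insulin-like growth factors, at 1481-fold (578 to 5438), BPIFB1 at 1416-fold (392 to 11695), CALCR, the calcitonin receptor, at 1304-fold (234 to 51539), and EMC10 at 988-fold (273 to 8163). CDKN2B, which encodes the CDK4/6 inhibitor p15, had 93.3 CPM in ED and no count in MCF7_E2, at least 481-fold higher against a floor of 3 counts. On the same floor, IL1R1 was at least 281-fold, CTSF at least 272-fold and DAB2 at least 262-fold higher. PSAT1, an enzyme of serine synthesis, had 84.6 CPM in MCF7_E2 and no count in ED, at least 773-fold lower. HES7, OLFM3 and FGB were at least 310-, 243- and 241-fold lower. FCGRT was lower 200-fold (85.2 to 618), SGCE 139-fold (53.8 to 514), INSYN1 132-fold (56.2 to 410), and the stress-induced cofactor gene NUPR1 128-fold (90.3 to 187).

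Of 35 measured estrogen-induced genes, 14 were lower, 8 higher and 13 neither in ED, with a median log2 ratio of -0.56, at percentile 0.07 of expression-matched random lists. SUSD3 was 41.8-fold (31.6 to 56.4), EGR3 13.1-fold (10.2 to 16.9) and MYB 5.41-fold (4.85 to 6.05) lower, and PGR, the progesterone receptor, was 2.98-fold (2.57 to 3.46) lower. CALCR, named above among the highest genes, is also on this list, and TFF1 was at 1061 CPM in ED and 1035 in MCF7_E2. None of the 10 estrogen-repressed genes was lower and 6 were higher (median 1.48, percentile 99.99), among them TGFB2 at 82.6-fold (22.7 to 685) and BCAS1 at 18.5-fold (17.1 to 20.1). ESR1, which encodes estrogen receptor alpha (ENSG00000091831, GRCh38 chromosome 6, 151656691 to 152129619), was 2.36-fold (2.27 to 2.45) higher. CREB1 (ENSG00000118260, chromosome 2, 207529737 to 207603431) was at 45.4 CPM in ED and 30.2 in MCF7_E2, 1.51-fold (1.35 to 1.68) higher and not called. The 23 CREB pathway components did not stand apart (median 0.07, percentile 44.1, 3 higher and 3 lower). CREB target genes did, with 10 of 28 lower, 5 higher and 13 neither (median -0.69, percentile 0.22). FOS was 21.3-fold (18.0 to 25.3), EGR1 17.2-fold (15.6 to 19.0), PER1 5.09-fold (4.69 to 5.53) and CREM 3.28-fold (2.88 to 3.74) lower, all of them early response or clock-related genes.

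In ED the mitotic list stood apart as lower, and the DNA replication and E2F list as higher by its median, with most of its members not called. None of 25 mitotic genes was higher, 16 were lower and 9 were neither (median -1.25, below every one of 10000 random lists); HMMR was 4.98-fold (4.33 to 5.75) and CDC20 4.30-fold (4.01 to 4.62) lower. The 26 DNA replication and E2F target genes had a median of 0.47 (percentile 98.3) with 2 called, MCM4 at 3.63-fold (3.37 to 3.91) and CCNE2 at 2.92-fold (2.18 to 3.97) higher. MKI67, the proliferation marker Ki-67, was at 163 CPM against 139 and not called. CDKN1A, which encodes the cell cycle inhibitor p21, was 2.52-fold (2.44 to 2.60) higher. RB1 and CDK6 were 2.10-fold (1.90 to 2.32) and 2.15-fold (1.97 to 2.34) higher, or log2 ratios of 1.07 and 1.10; the GC correction left them higher but below the threshold, at 0.78 and 0.84, and so did scaling by total counts, at 0.95 and 0.99. CCND1, which encodes cyclin D1, was 2.30-fold (2.27 to 2.34) lower by the deposited counts; its count in MCF7_E2, 36051, differs from the 26500.4 that the deposited FPKM value implies, and with the implied count its log2 ratio was -0.76 in place of -1.20, which is not called.

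The amino acid response genes, targets of ATF4, held 12 lower, 7 neither and none higher of 19 (median -1.43), and hypoxia and glycolysis genes 11 lower, 9 neither and none higher of 20 (median -1.32), both below every random list. PHGDH, the first enzyme of serine synthesis, was 52.6-fold (46.7 to 59.5) lower, and CA9, a hypoxia-induced carbonic anhydrase, 154-fold (52.2 to 753). Of 24 interferon-stimulated genes 14 were higher, 3 lower and 7 neither (median 1.55, or 1.46 with members at 0 counts set to their bound), with IFI6 at 6.21-fold (5.26 to 7.38) and OAS1 at 5.80-fold (4.03 to 8.62) higher. Of 10 inflammatory and NF-kB target genes 7 were higher and none lower (median 1.15, percentile 98.6), TNFAIP3 by 19.2-fold (10.6 to 38.7). Of 7 drug efflux transporters 6 were higher and none lower (median 1.98, percentile 99.99), ABCG2 by 7.68-fold (6.58 to 9.01). Lysosomal genes (median 0.69, 7 higher and 2 lower of 23, percentile 99.88) included CTSZ, 20.9-fold (10.5 to 48.9) higher. Among heat shock genes (median 0.93, 5 higher and 1 lower of 11, percentile 99.88) DNAJA1 was 4.23-fold (3.96 to 4.52) higher. After the GC correction, basal and stem-like markers (median 0.79) and apoptosis regulators (0.61) also stood apart as higher and cytosolic ribosomal proteins (-0.14) as lower. The share of higher genes among those called was 48.5% here and 72.4% from log2(FPKM + 0.5), a scale on which the median of all genes moved by 0.36 toward ED.

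**Figure D2:**
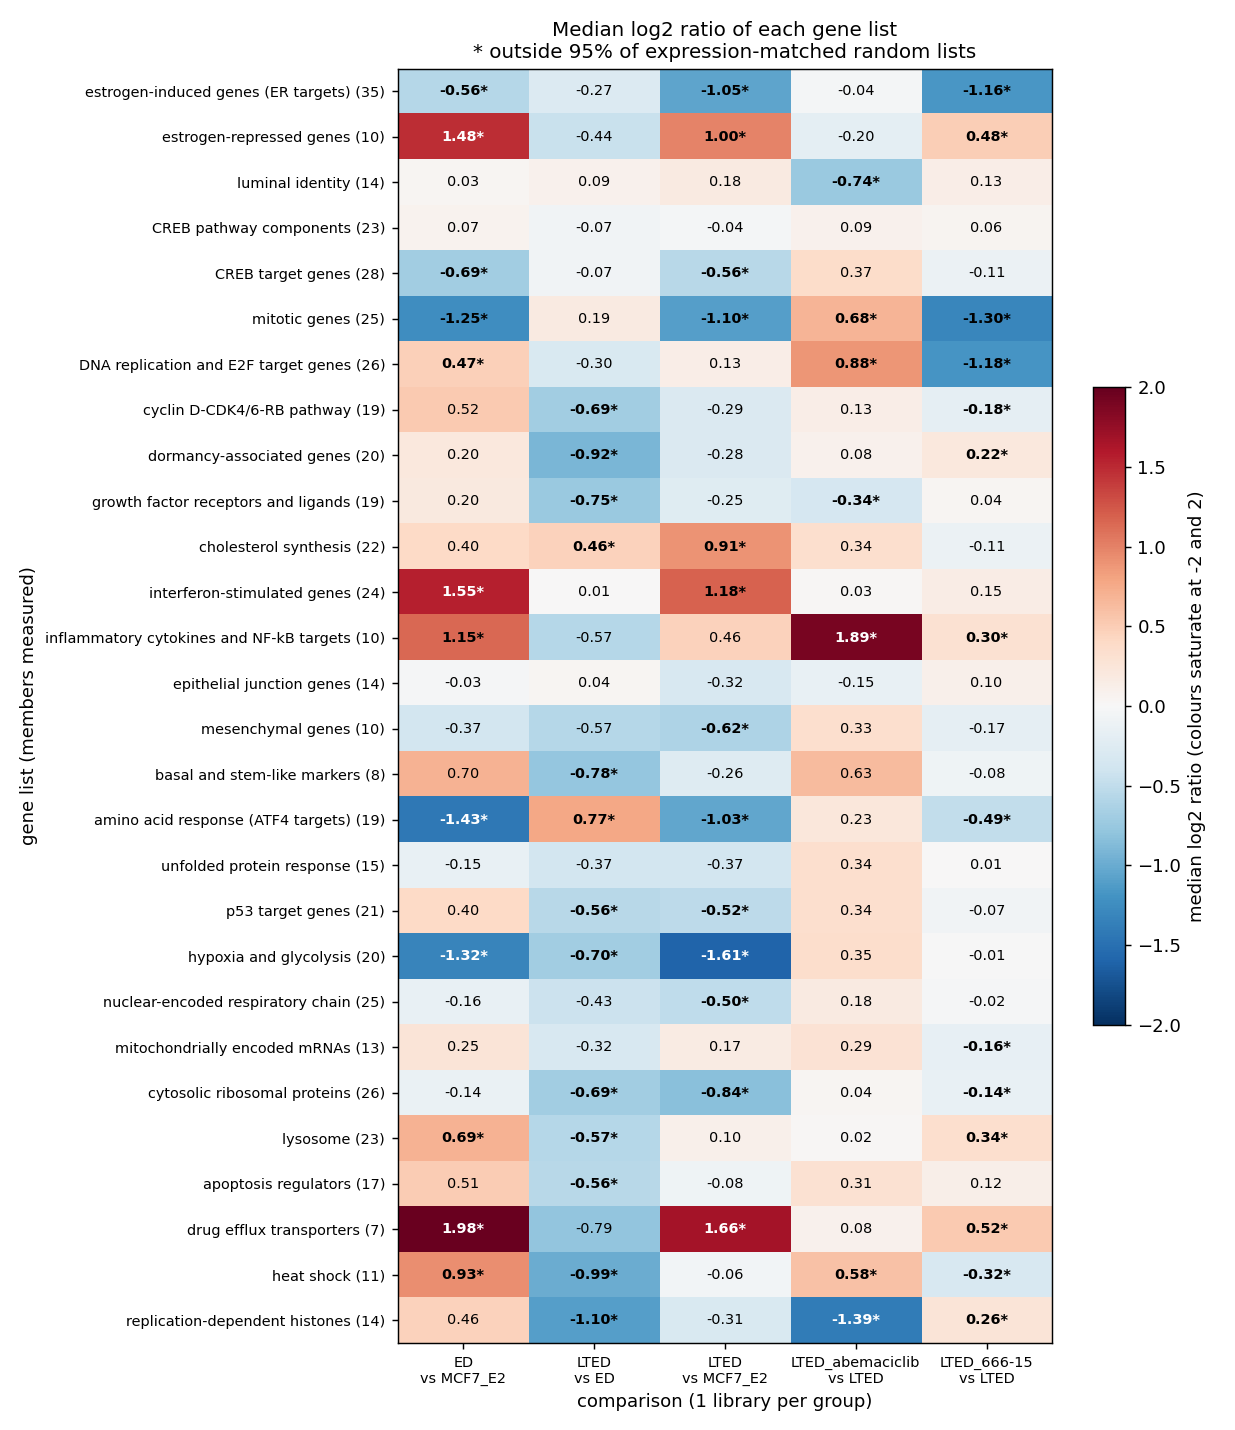
Median log2 ratio of each fixed gene list (rows) in the 5 comparisons of single libraries (columns); color and printed number give the median, and the mark shows lists that stand apart from 10000 expression-matched random lists. Mitotic genes stand apart at -1.25 in ED vs MCF7_E2 and at -1.30 in LTED_666-15 vs LTED, and at 0.68 in LTED_abemaciclib vs LTED.

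LTED was compared with ED to ask how cells after 13 months without estrogen differ from those after 1 month, which the series describes in terms of leaving dormancy. The lists of amino acid response and cholesterol synthesis genes stood apart as higher in LTED. Those of dormancy-associated, growth factor, ribosomal protein, heat shock, p53 target and hypoxia genes stood apart as lower. Many members of these lists were not called. Of 15431 genes tested, 2507 were higher and 2417 lower. PSAT1, at 37.1 CPM in LTED, was at least 339-fold higher, and SYNE1, the neighbor of ESR1 on chromosome 6, was 409-fold (334 to 508) higher. NUPR1 was higher 257-fold (182 to 377), DOCK3 62.4-fold (34.5 to 126), HSD17B14 59.8-fold (41.2 to 90.5), BRINP2 59.4-fold (40.3 to 91.5), GJC2 49.0-fold (33.2 to 75.5) and TCEA3 44.3-fold (30.2 to 67.7). KLK11, a kallikrein protease gene, was 4451-fold (799 to 175821) lower, with 1 count in LTED. EMC10, CDKN2B, CTSF and DAB2, the genes near 0 in MCF7_E2, had no count in LTED and were at least 744-, 543-, 307- and 295-fold lower. EPHA7, SDR42E1 and RAB32 were at least 249-, 225- and 194-fold lower. Of these highest and lowest genes, all but BRINP2 stood over 8-fold above or below every other library in ED. With 1 ED library, a change with longer deprivation cannot be told apart here from a different culture of MCF7 behind ED. The same limit holds for the lists in LTED vs ED.

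Of 19 amino acid response genes 8 were higher, 3 lower and 8 neither in LTED (median 0.77, above every random list), including PHGDH at 14.4-fold (12.7 to 16.3). Cholesterol synthesis genes held 8 higher, 14 neither and none lower of 22 (median 0.46, percentile 99.97), with the mevalonate pathway enzymes MVK at 5.17-fold (4.76 to 5.63) and MVD at 3.62-fold (3.48 to 3.76). Of 20 dormancy-associated genes 9 were lower, 2 higher and 9 neither (median -0.92, below every random list). This list did not stand apart in ED vs MCF7_E2 (median 0.20, percentile 76.9, 6 higher and 5 lower). Nor did it in LTED vs MCF7_E2 (median -0.28, percentile 7.64, 3 higher and 8 lower). In LTED vs ED, IGFBP5 was 55.8-fold (52.3 to 59.6), COL4A5 29.4-fold (20.5 to 43.7) and SOX9 4.07-fold (3.17 to 5.29) lower. NR2F1, a transcription factor gene on that list, had 21 counts in LTED, and its deposited counts and FPKM disagree in ED (124 counts against 154.1 implied); it was lower by either, at a log2 ratio of -1.83 or -2.14. Growth factor receptor and ligand genes held 8 lower, 2 higher and 9 neither of 19 (median -0.75, percentile 0.19), with AREG 12.5-fold (9.72 to 16.4) and RET 4.71-fold (4.45 to 5.00) lower; the list no longer stood apart from log2(FPKM + 0.5), at a median of -0.56.

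ESR1 was 4.56-fold (4.47 to 4.65) and PGR 4.76-fold (4.15 to 5.46) higher in LTED than in ED, but the estrogen-induced list did not stand apart (median -0.27, 6 higher and 13 lower of 35). CREB1 was 1.47-fold (1.33 to 1.63) lower and not called, and neither the CREB components (median -0.07, percentile 64.3) nor the CREB targets (median -0.07, percentile 44.8) stood apart. NR4A1, a CREB target, was 2.74-fold (2.40 to 3.14) lower. The mitotic list had a median of 0.19 (percentile 95.6), and of 0.47 (percentile 99.8) after the GC correction, where it stood apart. MKI67, a member of that list, was lower, 2.19-fold (2.06 to 2.34) at 74.1 CPM against 163, and BCL2, an inhibitor of apoptosis, 2.31-fold (1.93 to 2.78); the GC correction ended both calls, at log2 ratios of -0.99 and -0.98, and so did scaling by total counts. The cyclin D, CDK4/6 and RB list was lower (median -0.69, percentile 0.74), with CDKN1A 3.61-fold (3.48 to 3.74) lower, but not after the GC correction (median -0.47) or without the chromosomal blocks of shifted genes (median -0.51). CCND1 itself stood at 1024 CPM in LTED and 1013 in ED.

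Further lists lower in LTED than in ED were p53 targets (median -0.56, 6 lower and none higher of 21), with GDF15 at 3.67-fold (3.49 to 3.86), hypoxia and glycolysis (median -0.70, 4 lower and 1 higher of 20), with ALDOC at 15.3-fold (9.14 to 27.6), and cytosolic ribosomal proteins (median -0.69, 7 lower and none higher of 26), with RPL38 at 3.30-fold (3.14 to 3.48). Heat shock genes had a median of -0.99 (4 lower and 1 higher of 11), apoptosis regulators of -0.56 (6 lower and 1 higher of 17, or 3 lower and none higher after the GC correction), and basal and stem-like markers of -0.78 (2 lower and none higher of 8), among which SOX2 was 3.86-fold (3.43 to 4.35) lower. The lysosomal list (median -0.57) lost its call after the GC correction (median -0.34). Replication-dependent histones, whose main transcripts lack a poly(A) tail, had a median of -1.10, or -0.85 with members at 0 counts at their bound, with 7 of 14 lower. The share of higher genes among those called was 50.9%, against 68.5% by total counts and 23.2% from log2(FPKM + 0.5), on which the median of all genes moved by 0.27 and -0.33.

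Whether genes lower after 1 month were higher again after 13 months was read from the genes called in both comparisons, beside the number expected from independent calls. Among 14902 genes tested in both comparisons, 1381 were lower in ED than in MCF7_E2 and higher in LTED than in ED, against 336 expected. ED is the numerator of the first and the denominator of the second, so whatever is particular to that 1 library enters both and raises the count, which therefore does not show a return. Counting noise alone gave at most 4 in simulated libraries, which hold no variation between cultures. In the planned count without a shared library, genes lower in ED vs MCF7_E2 were crossed with those higher in LTED_abemaciclib vs LTED_666-15, and 405 were shared against 376 expected, or 396 against 274 after the GC correction. That later comparison holds no library at 1 month.

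LTED and MCF7_E2, both within 1 library set, compare long-deprived cells with cells kept in estrogen. As judged by list medians, estrogen-induced, mitotic, hypoxia, amino acid response and ribosomal protein genes were lower in LTED. Cholesterol synthesis, interferon-stimulated and estrogen-repressed genes were higher in the same sense. Of 15190 genes tested, 1720 were higher and 1544 lower. Highest were AKR1C3 at 153-fold (95.5 to 263) and AKR1C2 at 120-fold (91.7 to 160), closely related steroid-metabolizing reductase genes whose reads are hard to separate, GPNMB at 129-fold (81.4 to 218), BPIFB1 at 163-fold (44.8 to 1351) and CEACAM6 at 46.6-fold (37.0 to 59.4). INAVA was 36.6-fold (20.2 to 73.7), SLC9A2 35.6-fold (23.8 to 55.9) and the aldehyde dehydrogenase gene ALDH3A1 35.1-fold (24.2 to 53.1) higher. Lowest were BRINP3 at 100-fold (38.9 to 371), the estrogen-induced gene WISP2 at 94.4-fold (75.9 to 119), ALDOC at 68.4-fold (41.2 to 123), ATRNL1 at 58.3-fold (26.5 to 160) and AREG, which encodes amphiregulin, at 48.3-fold (37.6 to 63.0). WIPF1 was 46.4-fold (27.9 to 83.5), FGB 38.4-fold (21.7 to 74.9) and ANGPTL4 37.4-fold (27.7 to 51.8) lower.

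Of 35 estrogen-induced genes 19 were lower, 1 higher and 15 neither in LTED than in MCF7_E2 (median -1.05, below every random list), with SUSD3 9.35-fold (7.87 to 11.2) lower and GREB1 at a log2 ratio of -4.67 (24.1 to 27.1-fold lower). ESR1 itself was 10.8-fold (10.4 to 11.1) higher, at 2435 CPM against 226. The region around ESR1 on chromosome 6 was higher as a block: 21 of 23 neighbors, ESR1 left out, had a GC-corrected log2 ratio to MCF7_E2 above 0 in LTED, whether or not they were called, with a median of 1.01. In ED the same held for 15 of the 23, with a median of 0.32. Estrogen-repressed genes held 5 higher, 5 neither and none lower of 10 (median 1.00). CREB1 stood at 30.9 CPM in LTED and 30.2 in MCF7_E2, and the CREB components at a median of -0.04 (percentile 47.7, 1 higher and 2 lower of 23). CREB targets were lower, with 9 of 28 lower, 3 higher and 16 neither (median -0.56, percentile 0.16). FOS was 20.8-fold (16.9 to 25.7), EGR1 11.9-fold (10.7 to 13.2) and NR4A1 4.42-fold (3.87 to 5.06) lower. CCND1 was 2.28-fold (2.24 to 2.32) lower by counts; with the count that FPKM implies for MCF7_E2 the log2 ratio was -0.74 in place of -1.19, which is not called.

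**Figure D3:**
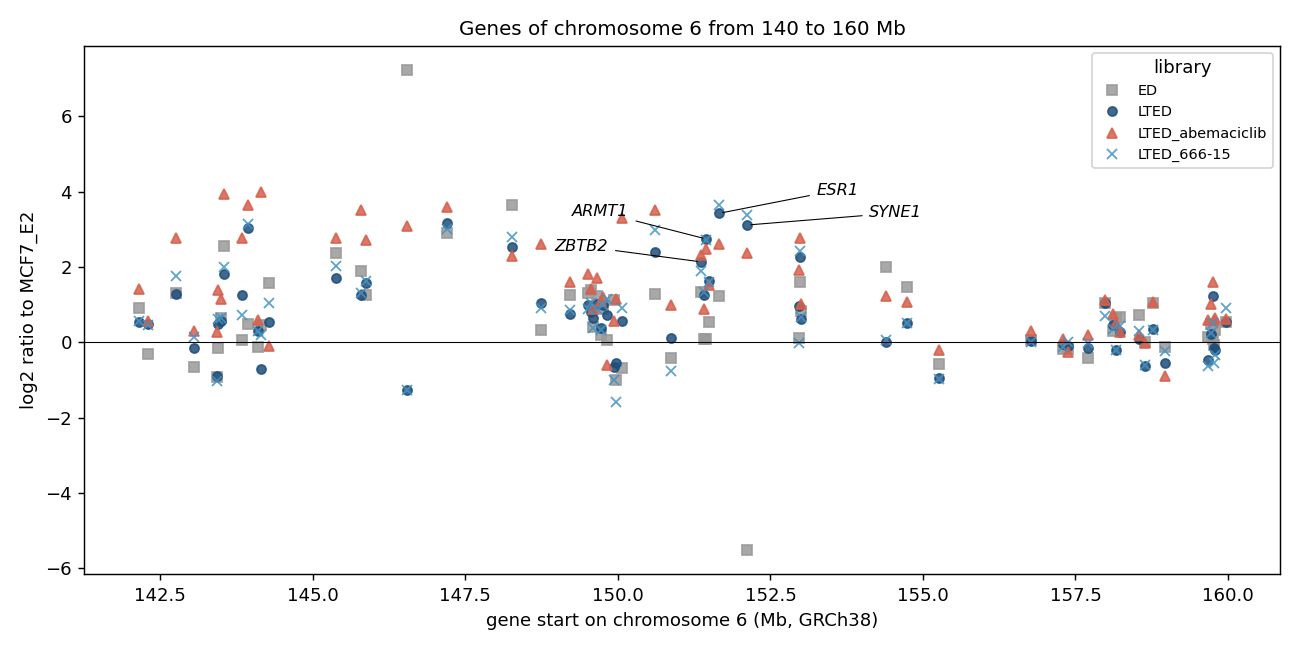
Log2 ratio to MCF7_E2, without GC correction, of each gene (points) by its start on chromosome 6 in Mb (GRCh38), with one symbol per library. ESR1 lies at 3.43 in LTED and 1.24 in ED, and SYNE1 is lower than MCF7_E2 in ED alone.

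**Figure D4:**
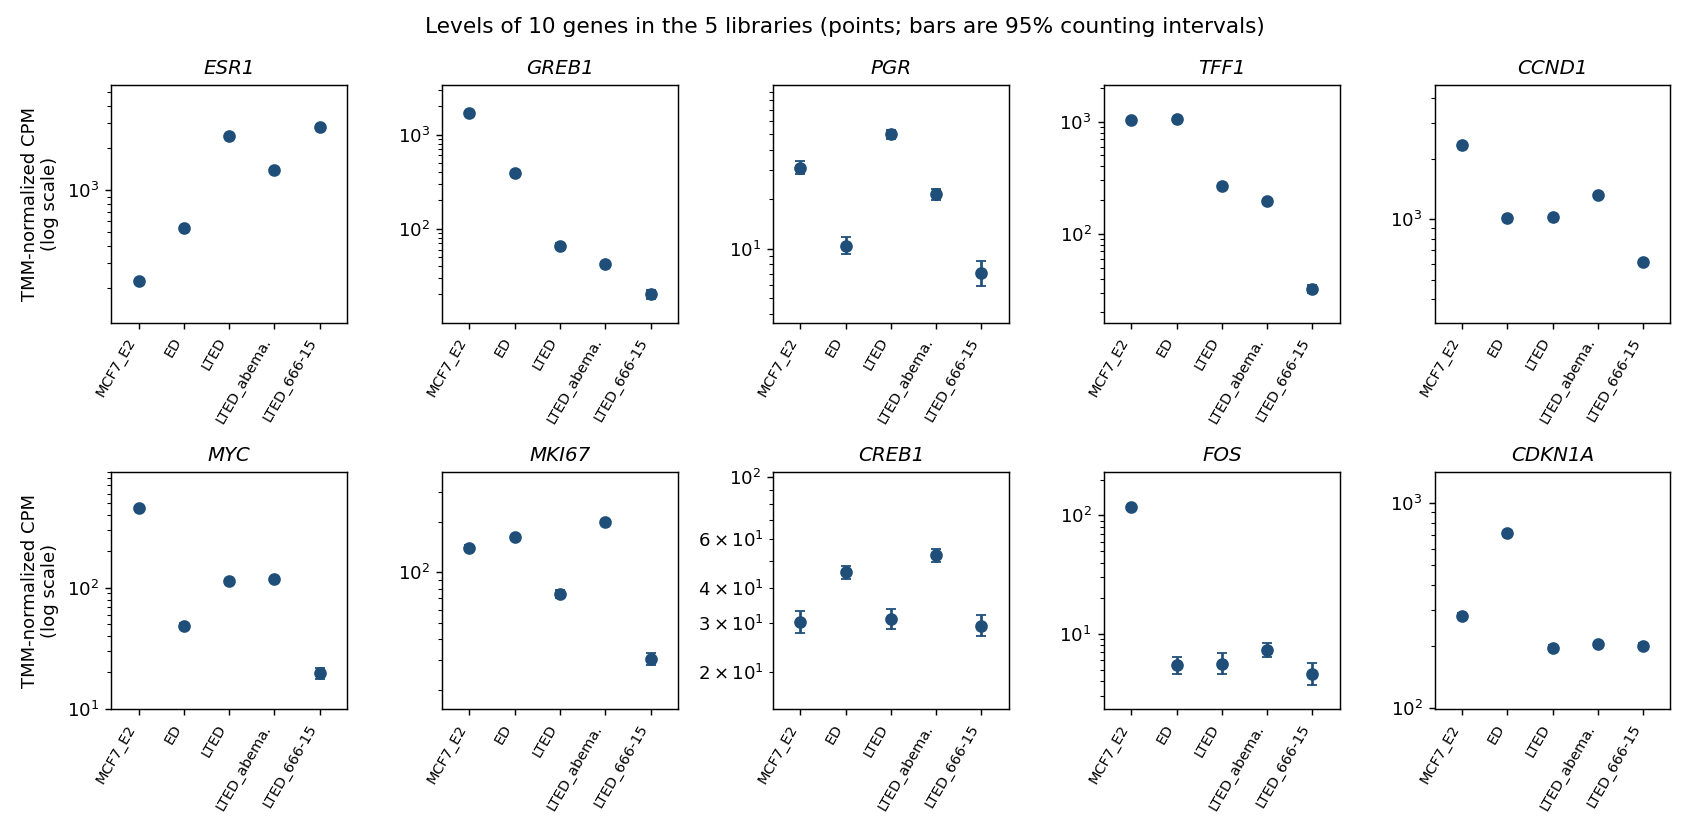
CPM of selected genes in the 5 libraries (log axis), with bars for the 95% Poisson interval of each single library. ESR1 goes from 226 in MCF7_E2 to 2435 in LTED, whereas CREB1 lies between 29.2 and 52.2 in all 5 libraries.

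Mitotic genes held 14 lower, 11 neither and none higher of 25 in LTED (median -1.10), with UBE2C 3.06-fold (2.84 to 3.30) lower, while the DNA replication and E2F list had a median of 0.13 (percentile 89.5). Of 20 hypoxia and glycolysis genes 15 were lower and none higher (median -1.61): NDRG1 was 11.3-fold (10.6 to 12.1) lower and CA9, with no count in LTED, at least 98.2-fold. Amino acid response genes held 11 lower, 1 higher and 7 neither of 19 (median -1.03), with the folate enzyme gene MTHFD2 4.76-fold (4.52 to 5.01) and the amino acid transporter SLC7A5 3.81-fold (3.75 to 3.87) lower. Ribosomal protein genes (median -0.84, 6 lower and none higher of 26), nuclear-encoded respiratory chain genes (median -0.50, 3 lower and none higher of 25) and p53 targets (median -0.52, 4 lower and 1 higher of 21) were lower as lists; GDF15 was 5.75-fold (5.47 to 6.06) lower. Log2 ratios in this comparison rose with gene length (Spearman coefficient 0.172). Whether that trend contributes to these medians was not tested. Cholesterol synthesis genes held 8 higher and none lower of 22 (median 0.91), with LSS at 4.68-fold (4.47 to 4.90). Interferon-stimulated genes held 14 higher, 4 lower and 6 neither of 24 (median 1.18), with OAS1 at 8.80-fold (6.11 to 13.1). Drug efflux transporters had 3 of 7 higher (median 1.66, or 0.82 with the member at 0 counts at its bound), among them ABCC3 at 3.39-fold (3.19 to 3.61). Mesenchymal genes were lower (median -0.62, 3 of 10), a call that the GC correction ended (median -0.55). The share of higher genes was 52.7%, against 64.9% by total counts, on which the median of all genes moved by 0.16.

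LTED_abemaciclib was set against LTED to describe long-deprived cells kept under a CDK4/6 inhibitor, which the treatment protocol describes as resistant to it. The labels name no vehicle-treated culture of the same age. An effect of the drug and a selection of resistant cells therefore cannot be told apart. The DNA replication, mitotic and NF-kB target lists stood apart as higher in LTED_abemaciclib, and the luminal identity list as lower, though many of their members were not called. Of 15142 genes tested, 1812 were higher and 2284 lower; after the GC correction 1263 were higher and 2029 lower, of which 1057 and 1686 were among those called without it. GBP1, an interferon-induced GTPase gene, had 30.4 CPM and no count in LTED, at least 177-fold higher. CTGF, a target of the YAP coactivator, was higher 180-fold (91.0 to 416), CYP1A1, a target of the aryl hydrocarbon receptor, 101-fold (83.1 to 124), FHL2 63.3-fold (40.9 to 104), PLS3 58.3-fold (32.4 to 117), STEAP4 47.6-fold (25.7 to 99.6), FAR2 26.8-fold (15.9 to 49.3) and CASP4 23.2-fold (14.9 to 38.1). PCDH19 was lower 29.6-fold (20.4 to 44.7), KIAA1324 19.6-fold (17.1 to 22.6), SLIT1 18.6-fold (14.5 to 24.0), BRINP2 16.7-fold (13.6 to 20.7), PMP22 16-fold (13.8 to 18.6), DNM1 16-fold (13.3 to 19.6), SGCG 14.2-fold (11.5 to 17.7), and GFRA1, a co-receptor of RET, 12.1-fold (11.4 to 13.0).

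Of 26 DNA replication and E2F target genes 9 were higher and none lower under abemaciclib (median 0.88, above every random list). MCM10 was 3.19-fold (2.79 to 3.65), CCNE1, which encodes cyclin E1, 2.73-fold (2.34 to 3.20), and RRM2 2.72-fold (2.52 to 2.93) higher. Mitotic genes held 7 higher, 18 neither and none lower of 25 (median 0.68, percentile 99.93); after the GC correction the list still stood apart, at a median of 0.36 (percentile 99.3), with 3 members higher. MKI67 was 2.68-fold (2.52 to 2.84) higher; CENPF at 2.73-fold (2.54 to 2.94) and CDK1 at 2.49-fold (2.26 to 2.74) were below the threshold after the GC correction, at log2 ratios of 0.92 and 0.72 in place of 1.45 and 1.31. RB1, the target of CDK4/6, was at 38.2 CPM against 38.7, CDK6 at 92.5 against 49.7 (log2 ratio 0.90, and 1.14 from FPKM, where it is called), and CDKN1A at 205 against 197. The cyclin D, CDK4/6 and RB list did not stand apart (median 0.13), but did after the GC correction (median 0.43, percentile 99.2).

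Of 14 luminal identity genes 5 were lower and none higher (median -0.74, percentile 0.01), with MLPH 3.83-fold (3.76 to 3.91) and SPDEF 3.36-fold (3.21 to 3.52) lower. ESR1 was at 1391 CPM against 2435, and PGR was 2.32-fold (2.09 to 2.57) lower by counts but not called from FPKM (log2 ratio -0.65). The estrogen-induced list had a median of -0.04. Of 10 NF-kB target genes 5 were higher and none lower (median 1.89, above every random list): LIF was 21.8-fold (17.5 to 27.4), BIRC3 13.3-fold (9.29 to 19.7) and TNFAIP3 4.83-fold (4.07 to 5.76) higher. BIRC3 and CASP4 lie on the long arm of chromosome 11, where 39 of 42 expressed genes between 100 and 114 Mb had a GC-corrected log2 ratio to MCF7_E2 above 0, whether or not they were called, with a median of 0.92. CREB1 was 1.69-fold (1.53 to 1.86) higher, at 52.2 CPM, and not called. Its levels split by library set, at 45.4 CPM in ED against 30.2 in MCF7_E2, 30.9 in LTED and 29.2 in LTED_666-15. Its differences in the comparisons that cross the sets therefore cannot be told apart from the set. CREB targets stood at a median of 0.37 (percentile 95.5, 6 higher and 3 lower of 28), and at 0.43 (percentile 99.8) after the GC correction, where they stood apart. Growth factor genes were lower (median -0.34, percentile 2.36, with ERBB4 3.03-fold lower, 2.75 to 3.34), but the call ended after the GC correction (median -0.28) and the median was 0.02 from log2(FPKM + 0.5). The heat shock list (median 0.58) lost its call to the GC correction (median 0.30), while mesenchymal genes (0.48) and p53 targets (0.34) stood apart as higher only after it. Histones were lower (median -1.39, 8 of 14), with 12 of the 14 in the histone cluster on the short arm of chromosome 6, where 23 other coding genes had a median of -0.57. The share of higher genes was 44.2%, against 32.0% by total counts and 78.6% from log2(FPKM + 0.5), on which the median of all genes moved by -0.16 and 0.35.

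LTED_666-15 was compared with LTED to describe long-deprived cells after 24 hours with a CREB inhibitor; the labels name no vehicle-treated culture here either. Estrogen-induced, mitotic and DNA replication genes were lower in LTED_666-15, whereas the lists of CREB components and CREB targets did not stand apart. Of 14981 genes tested, 168 were higher and 531 lower. The share of higher genes was 24.0%, against 6.7% with at least 5 CPM (22 higher and 304 lower) and 13.4% from log2(FPKM + 0.5) (29 and 187). TFF1, an estrogen-induced secreted peptide gene (ENSG00000160182, chromosome 21, 42362282 to 42366594), was 8.29-fold (7.61 to 9.05) lower, at 32.4 CPM against 269. RNF223 was lower 7.29-fold (5.77 to 9.32), PGR 6.99-fold (5.80 to 8.49), IGFBP4 5.85-fold (5.53 to 6.20), MYC 5.74-fold (5.13 to 6.45), BRINP2 5.27-fold (4.51 to 6.19) and MUC5B 4.49-fold (4.07 to 4.96). U2AF1L5 was 8.88-fold (6.84 to 11.7) lower, but it is a near-identical copy of U2AF1 and its count is uncertain. On the other side, 4 coding genes above the expression limit were called: SLIT1 at 2.64-fold (2.43 to 2.87), LIMCH1 at 2.17-fold (1.76 to 2.70), CHRD at 2.09-fold (1.79 to 2.45) and IL17REL at 2.07-fold (1.66 to 2.60), of which SLIT1 alone was called from log2(FPKM + 0.5) as well.

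None of 35 estrogen-induced genes was higher in LTED_666-15, 22 were lower and 13 neither (median -1.16, below every random list), while ESR1 stood at 2821 CPM against 2435. Estrogen-repressed genes had a median of 0.48, above every random list, with none of 10 called. Mitotic genes held 23 lower, 2 neither and none higher of 25 (median -1.30), with MYBL2 3.10-fold (2.86 to 3.36) and AURKB 2.76-fold (2.43 to 3.15) lower. DNA replication and E2F targets held 16 lower, 10 neither and none higher of 26 (median -1.18), with RRM2 2.92-fold (2.56 to 3.34) and UHRF1 2.86-fold (2.51 to 3.26) lower. MKI67 was 2.43-fold (2.20 to 2.69) lower. CREB1 was at 29.2 CPM against 30.9, the 23 CREB components had none called (median 0.06, percentile 81.6), and of 28 CREB targets 3 were lower, 25 neither and none higher (median -0.11, percentile 7.02). Of the named CREB targets, CCNA2 was 2.79-fold (2.44 to 3.19) lower, CCND1 was at 611 CPM against 1024, and FOS and NR4A1 differed by 1.22-fold (0.898 to 1.65) and 1.00-fold (0.845 to 1.18), intervals that include no difference.

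The other lists that stood apart in LTED_666-15 had small medians and at most 2 members called. Amino acid response genes (median -0.49) included SLC7A5, 2.45-fold (2.38 to 2.51) lower, and the cyclin D, CDK4/6 and RB list (median -0.18) included RBL1, 2.59-fold (2.04 to 3.32) lower. Heat shock genes (median -0.32), cytosolic ribosomal proteins (-0.14) and mitochondrially encoded mRNAs (-0.16) were lower with no member called. Drug efflux transporters (median 0.52), lysosomal genes (0.34), dormancy-associated genes (0.22), NF-kB targets (0.30) and histones (0.26) were higher as lists, the NF-kB list not from log2(FPKM + 0.5), where its median was 0.19, and apoptosis regulators only after the GC correction (0.13); NR2F1 on the dormancy list had 56 counts against 21.

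To ask whether genes higher after long deprivation are those lower under CREB inhibition, genes higher in LTED than in ED were crossed with genes lower in LTED_666-15 than in LTED. Of 14707 genes tested in both, 154 were shared against 90.5 expected. LTED is the numerator of the first comparison and the denominator of the second, so whatever is particular to that 1 library raises the count. Counting noise alone, with LTED shared, gave at most 6 in simulated libraries, which hold no variation between cultures. With LTED_abemaciclib vs ED as the first comparison no library was shared, and 206 genes were shared against 75.5 expected. That comparison adds abemaciclib to the long deprivation. The DNA replication and mitotic lists were higher in LTED_abemaciclib than in LTED (medians 0.88 and 0.68) and lower in LTED_666-15 (-1.18 and -1.30). Their genes were not removed from this overlap, so it does not answer the question for deprivation alone.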

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

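The GC-corrected values, TMM without ED, the calls without positional blocks and the counts implied by FPKM were chosen after seeing the data; the other alternatives were planned. None of the genes called turned to the other side under any alternative run. Of 17 counts, all stayed within 1.5 times the value reported with DESeq2 size factors, a prior count of 0.5 and the GC correction, and so did the 15 run on thinned counts, the 15 run without positional blocks, the 6 run with TMM factors without ED and the 5 run with unmatched random lists. The counts that moved further follow, as higher then lower genes. With a log2 ratio of at least 1.5 they were 1527 and 1596 (ED vs MCF7_E2), 1410 and 1227 (LTED vs ED), 924 and 724 (LTED vs MCF7_E2), 712 and 1195 (LTED_abemaciclib vs LTED) and 37 and 152 (LTED_666-15 vs LTED), with 34 and 717 genes in the 2 overlaps; a stricter threshold calls fewer genes by construction. With at least 5 CPM, fewer genes were tested, and 1749 were lower in ED vs MCF7_E2, 1397 higher in LTED vs ED, 894 higher in LTED vs MCF7_E2, 1256 lower in LTED_abemaciclib vs LTED, and 22 and 304 higher and lower in LTED_666-15 vs LTED, with overlaps of 60 and 772. Without a filter more genes were tested, and 3778 were higher in LTED vs ED, 3469 lower in LTED_abemaciclib vs LTED and 326 higher in LTED_666-15 vs LTED, with 248 in the overlap of LTED vs ED with LTED_666-15. A prior count of 10 gave 82 higher genes in LTED_666-15 vs LTED and 98 in that overlap. Coding genes alone gave 1652 higher in LTED vs ED, 76 higher in LTED_666-15 vs LTED and 97 in that overlap. With log2(FPKM + 0.5), 1085 genes were lower in ED vs MCF7_E2, 861 higher in LTED vs ED, 794 and 872 higher and lower in LTED vs MCF7_E2, 672 lower in LTED_abemaciclib vs LTED, and 29 and 187 in LTED_666-15 vs LTED, with overlaps of 28 and 410. With log2(FPKM + 0.1), 1642 genes were lower in ED vs MCF7_E2, 1475 higher and 3654 lower in LTED vs ED, and 3290 higher and 1212 lower in LTED_abemaciclib vs LTED. Part of the change on FPKM is its library total, which moves all genes by 0.38, -0.35, 0.02, 0.37 and 0.05 in the order of the comparisons. Calls on FPKM also dropped the counting interval and added a fixed constant. How much each of these contributes was not tested. Scaling by total counts left 1604 lower in LTED vs ED, where it moves the median of all genes by 0.27. The planned count without a shared library for the second overlap, of genes lower in ED vs MCF7_E2 with those higher in LTED_abemaciclib vs LTED_666-15, was 405 against 376 expected, and 396 against 274 after the GC correction; its later comparison holds no library at 1 month, so it says nothing about a return. Of 140 list medians, over all alternatives, 1621 values kept their call, 30 lost one and 29 gained one; of 312 values for named genes, 1201 kept, 44 lost and 8 gained it. Leaving out replicates and tests over columns were not run, as each group has 1 library with 1 column. Depth limits what can be said of genes under a few CPM, since 3 counts are 0.101 to 0.194 CPM.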

Other observations

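The tests of explanations in this part were all chosen after the results they bear on had been seen, as were the genes CDKN2A, MTAP and YAP1; the gene lists were fixed earlier. ED expressed the CDK4/6 inhibitor genes of chromosome 9 that the other libraries nearly lacked: CDKN2B stood at 93.3 CPM and CDKN2A at 4.85 CPM, while MTAP, their neighbor, stayed at or below 0.69 CPM in all 5 libraries. CDKN2B had no count outside ED, and CDKN2A had at most 3. These genes cannot tell a response to deprivation from a culture that differs, as ED is 1 library. Under abemaciclib, CTGF stood at 82.3 CPM, and YAP1, whose product activates it, stood at 196 CPM against 122 in LTED, a difference below the threshold for a call. YAP1 starts at 102110461 on chromosome 11. It lies in the stretch from 100 to 114 Mb where 39 of 42 expressed genes were above 0 against MCF7_E2 (median 0.92). Its difference may therefore be that of its neighbors. Epithelial junction genes stood apart in none of the comparisons, with medians from -0.32 to 0.10, and neither did the unfolded protein response, with medians from -0.37 to 0.34. Of the markers of other cell types, none of 11 leukocyte genes reached 1 CPM in any library, and 3 fibroblast and 3 endothelial genes did. The fibroblast genes had medians of 0.91 in ED vs MCF7_E2 and -0.32 in LTED vs ED, and the endothelial genes of -0.82 and 1.39. Gene symbols read as dates appear in the deposited count table (5-Mar and 9-Mar), which does not affect their identifiers.

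The first pattern is the trend with GC content between libraries. After thinning all libraries to the lowest total, the Spearman coefficient of LTED_abemaciclib vs LTED was still -0.51. Thinning keeps the expected ratio of each gene, so it bears on counting noise alone. It cannot decide whether the way the deeper libraries were made or sequenced matters. A separate preparation or sequencing of ED and LTED_abemaciclib may underlie the trend. The smallest coefficient across the sets, 0.286 in size, exceeded the largest within a set, 0.136. That prediction was written after the trend had been seen, so its result restates the trend and does not test the cause. A response of the cells that follows GC content stays open, with a coefficient of -0.51 before thinning, because no group has a library in both sets. The 2 sets also differ in the total that FPKM implies, 0.967 and 1.03 times the counts against 1.36 to 1.49 times.

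The second pattern is blocks of neighboring genes that shift together. The lowest window of 15 genes in ED vs MCF7_E2 had a GC-corrected median of -1.67 (chromosome 7, 73.5 to 74.6 Mb, lowest of 200 shuffles -1.43), the highest in LTED vs MCF7_E2 1.31 (chromosome 6, 142.3 to 148.6 Mb, highest shuffle 1.00), and the highest in LTED_abemaciclib vs LTED 1.25 (chromosome 11, 102.4 to 108.9 Mb, highest shuffle 1.00). GC content as the whole cause is argued against in all 3, and LTED_666-15 vs LTED had no window beyond its shuffles. LTED vs ED had the most such windows, 65 above and 21 below its shuffles, covering 208 genes. Its highest was 1.46 (chromosome 19, 57.6 to 58.3 Mb, highest shuffle 1.22). Its lowest was -1.24 (chromosome 12, 57.6 to 58.9 Mb, lowest shuffle -1.09), in a window that holds CDK4. The window that holds ESR1 in LTED vs MCF7_E2 (chromosome 6, 149.7 to 153.0 Mb) is a separate one, at 1.04 just above the highest shuffle. For the neighbors of ESR1, a change carried by the cells derived from LTED is a candidate explanation, since 82.6% of the 23 had a GC-corrected log2 ratio of LTED_abemaciclib to ED above 0, libraries that did not define the block, but 15 of the 23 were above 0 in ED vs MCF7_E2 as well (median 0.32), which that explanation does not cover. Gains or losses of DNA could give such blocks, but no DNA was measured, and regulation over a region stays open.

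The third pattern is how far ED stands from the rest: 96 genes were over 8-fold above all 4 other libraries and 25 over 8-fold below, against 21 and 32 for MCF7_E2 and 21 and 9 for LTED_abemaciclib. LTED and LTED_666-15 correlated at 0.988 across genes, so neither can stand far from all others and their counts are not informative. A minority of other cells mixed into cells like those of MCF7_E2 is argued against as the whole cause by the 25 genes, each at 5 CPM or more in the others, which a minority could not remove. A culture of MCF7 that differs from the one behind the other libraries stays open: 30.1% of the genes called in ED vs MCF7_E2 were within 2-fold of MCF7_E2 in all 3 later libraries, a share that decides neither way, and 1 library cannot separate a culture from its treatment. The regions on chromosomes 17 (55 to 65 Mb) and 20 (47 to 62 Mb) were expressed above the rest of the genome in ED by log2 medians of 1.52 and 1.62, beside 1.06 and 1.70 in MCF7_E2, but chromosome 7 (66 to 77 Mb) by 0.37 in ED against 1.76 in MCF7_E2, 1.77 in LTED, 1.33 in LTED_abemaciclib and 1.66 in LTED_666-15.

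A hypothesis from the lists is that 24 hours of the CREB inhibitor and estrogen deprivation lower an overlapping set of genes. LTED_666-15 vs LTED and ED vs MCF7_E2 share no library. Of 14234 genes tested in both, 170 were lower in both against 78.6 expected, 43 were higher in both against 14.4 expected, and 63 were higher in ED and lower in LTED_666-15 against 66.5 expected. In LTED vs MCF7_E2 and LTED_666-15 vs LTED, which share the LTED library and were not simulated, 114 genes were lower in both against 42.6 expected from independent calls. Without the 51 mitotic, DNA replication and E2F genes on the lists, 155 were lower in both ED vs MCF7_E2 and LTED_666-15 vs LTED against 71.8 expected, a ratio of 2.16, so the listed cell cycle genes are not the whole of it. Other cell cycle genes outside the lists may still contribute, and the overlap does not say through which factor either condition acts. Log2 ratios rose with gene length in ED vs MCF7_E2 (Spearman coefficient 0.172) and in LTED_666-15 vs LTED (0.140). A trend in the same direction could raise the counts lower in both and higher in both. Whether it contributes to them was not tested.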
